A study of Mus musculus with 12 samples.

How the data were processed

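Each of the 12 libraries came as 1 table of gene symbols with an FPKM value (fragments scaled to transcript length and library size), the unit per the file headers. The libraries were made from TRI Reagent RNA with SMART-Seq HT cDNA and Nextera XT kits, per the labels. Per the submitters' processing notes, TopHat2 2.1.1, Bowtie2 2.2.8, SAMtools 0.1.18 and Cuffdiff 2.2.1 were used with the mm10 build. The annotation, read filters, strand setting and the scaling of FPKM between libraries are not given in the sources used here. The tables held 24346 gene symbols, and no 2 libraries were identical. Read counts are not used here, so no count model was fitted.

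Values were used as deposited, on the scale log2(FPKM + 1), and 11808 genes with at least 1 FPKM in at least 3 libraries were kept. Tests were run in R 4.3.3 with limma 3.58.1 (lmFit, eBayes with a trend), in 1 model of 4 group means that left 8 residual degrees of freedom. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes kept, and the threshold was an adjusted p under 0.05. The comparisons were RFP+ minus RFP- within B16F10, the same within MC38, the mean of both, the difference between both, and B16F10 minus MC38 over both gates. Levels are group means with the SD of 3 libraries, and log2 differences carry their SE. P-values measure the spread between libraries. The design text gives 3 mice, but no label ties a library to an animal, so that spread may be partly technical. The Y-linked gene Eif2s3y was present or nearly absent by title number, alike in both gates. Part of the spread is therefore between animals. Tables were read with jsonlite 2.0.0 and Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 made the depth values and the plots.

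Gene lists were tested with limma's camera, with a preset correlation between genes of 0.01 and with the correlation estimated from the data, and with fry. A list was tested with at least 5 genes kept, and camera and fry p-values were adjusted over the 22 functional lists and, apart from these, over the 5 cell type lists large enough. The functional lists were hypoxia response, glycolysis, oxidative phosphorylation, alternative activation without Arg1, classical activation, type I interferon response, interferon gamma response with CXCR3 ligands, MHC class II and class I presentation, chemokines, complement and resident-like macrophage genes, lipid-associated macrophage genes, monocyte-like genes, matrix remodelling, immune suppression, arginine and polyamine metabolism without Arg1, lysosome, cholesterol synthesis, unfolded protein and integrated stress response, oxidative stress with heme and iron, immediate early and dissociation genes, and cell cycle. The 11 cell type lists covered macrophage core, melanocytic, epithelial, T cell, NK cell, B cell, neutrophil, dendritic cell, fibroblast, endothelial and platelet genes. Counts "adjusted over the list alone" apply the Benjamini-Hochberg method to 1 list.

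The comparisons, the tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined, apart from what is stated here as chosen later. The rule named 14 focus genes in both within-tumour comparisons, and the 8 largest log2 differences in each direction among genes past the threshold with a mean of at least 5 FPKM and no overlap between the groups. For 3 libraries against 3, chance gives 10% of genes no overlap in either direction. Predicted or unnamed genes, microRNAs and snoRNAs were left out, and where none passed, the 4 with the smallest unadjusted p were named as not past the threshold. The rule also took up to 4 members past the threshold of each called list and up to 10 genes for the difference between tumours. For the mean of both tumours, overlap was judged within each tumour, a reading settled after the data were seen. Genes named outside the rule are stated as chosen after their values were seen.

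The title numbers (12, 11 and 3 in B16F10, 1 to 3 in MC38) stand in both gates, so pairing was checked. Across genes, deviations from the group means had r from 0.228 to 0.443 in the 6 pairs of libraries with the same number, all over the limit of 0.1, and r from -0.306 to 0.0178 for different numbers. The fit with the number as a block (4 residual degrees of freedom) was chosen beforehand as a further fit and is given beside the fit without it where it changed a call or moved a count of calls by over 1.5 times. For B16F10 minus MC38 the number was a random block, with a correlation of 0.291. The naming rule was applied to the block fit as well, a step added after the pairing check.

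Further fits chosen beforehand used pseudocounts of 0.1 and 5, no filter, a filter of 5 FPKM, quantile normalization, upper-quartile scaling, a fit of the compared groups alone, the block, array weights, a log2 difference of at least 1, the estimated correlation, and each library left out in turn. Chosen after seeing the data were the overlap of the tumours without Arg1, the block without the B16F10 number 12 pair, and a scaling of each library to the mean of its macrophage core genes. That scaling was redefined once after its first output was seen, from a shift of log2 values to a scaling of FPKM before the pseudocount was added.

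Simulated data of the same size, with 5 draws for each size of change and pairs that shared 0.5 of the variance, gave the reach of the tests. A log2 change of 1 was recovered for 55% of changed genes in B16F10, 58.4% in MC38, 83% over both and 18.8% for the difference, and a change of 2 for 94%, 93.2%, 98.2% and 75%. With the block a change of 1 gave 74.4%, 71.8%, 92.8% and 37.4%. False calls per simulation were 0 to 0.6 without the block and 5.6 to 8 with it. A list shifted by 0.5 was called in 5 of 5 draws with either correlation, and no other list was. Genes were drawn independently, but the estimated correlation was 0.55 for MHC class II and 0.66 for type I interferon genes. The draws cannot show how often the preset correlation calls lists of correlated genes falsely.

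Relative depth was read from the ratios between genes at or under 0.5 FPKM in a pair of libraries, which peak where both hold the same small number of reads, in bins of 0.02 log2. The peaks fitted together to within 0.05 log2 in 63 of 66 pairs of libraries. Peaks were set against MC38 RFP- number 2, so the pairs that include it fit by construction. Coordinates are those of GRCm38 (the same assembly as mm10) in GENCODE M21, found for 166 of the 168 named genes with 1 locus each. Left out were isoforms, splicing and sequence variants, which are not analysed here. Genes of close families, such as the H2 and Clec4 genes, may share reads, and how these were assigned is not given in the sources used here.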

Results

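Gene expression was measured by bulk RNA-seq in macrophages sorted from mouse tumours. The mice carried an Arg1-RFP reporter, a red fluorescent read-out of arginase 1, the enzyme that turns arginine into ornithine and urea. The tumours were B16F10, a melanoma line, or MC38, a colon adenocarcinoma line. The sorted cells were CD45+ MHCII+ F4/80+ CD11b+ and lacked Ly6C, Ly6G, NK1.1, B220 and CD90.2, and were parted into reporter-positive (RFP+) and reporter-negative (RFP-) cells. The 12 libraries formed 4 groups of 3. Total FPKM per library ran from 614875 to 815591, and 10445 to 11103 genes reached 1 FPKM. Read totals are not used here. From the smallest values, 1 read was worth 3.02 to 3.62 times as much FPKM in the B16F10 libraries as in the deepest MC38 library, and up to 1.18 times in the other MC38 libraries. The B16F10 libraries were thus the shallower ones. The highest total belonged to B16F10 RFP- library number 12, which also had the most genes listed at 0 (10597, against 8479 to 10081). Across genes, which are not independent replicates, it correlated with the other B16F10 libraries at r from 0.938 to 0.961, where these gave 0.964 to 0.983 among themselves.

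The first comparison asked what set RFP+ apart from RFP- macrophages within B16F10 tumours. Arg1, which the gate reads out, was 724 ± 167 FPKM in RFP+ and 81.5 ± 38.2 FPKM in RFP- cells (SD, n = 3 libraries each), a log2 difference of 3.21 ± 0.27 (SE, limma adjusted p = 0.000251). Spp1, which encodes the secreted glycoprotein osteopontin, rose from 551 ± 129 to 3687 ± 881 FPKM (SD, n = 3 each), a log2 difference of 2.74 ± 0.30 (limma adjusted p = 0.0015). Ppbp, a CXC chemokine gene best known from platelets, rose from 5.91 ± 5.29 to 109 ± 58.2 FPKM (log2 4.10 ± 0.61, limma adjusted p = 0.0211). The matrix proteases Mmp12 (log2 2.32 ± 0.34) and Mmp13 (2.16 ± 0.38), the lysosomal protease Ctsl (1.74 ± 0.16), the proton pump subunit Atp6v0d2 (2.27 ± 0.41) and the fatty acid receptor Cd36 (1.60 ± 0.27) rose too, with limma adjusted p of 0.0211, 0.0499, 0.000376, 0.0499 and 0.0431. Of these genes Arg1, Spp1, Ppbp, Mmp12, Ctsl and Atp6v0d2 also passed after scaling to the macrophage core genes, while Cd36 (log2 1.43, adjusted p = 0.15) and Mmp13 (2.02, adjusted p = 0.109) kept most of their difference and did not pass in limma.

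Of 6 genes lower in B16F10 RFP+ cells, 4 were MHC class II genes, whose products present peptides to CD4 T cells. H2-Ab1 fell from 2218 ± 918 to 728 ± 124 FPKM (log2 -1.54 ± 0.26, limma adjusted p = 0.0431). H2-Aa (-1.48 ± 0.26), H2-Eb1 (-1.56 ± 0.26) and H2-DMb1 (-1.26 ± 0.18) fell with limma adjusted p of 0.0499, 0.0431 and 0.0211. All 4 calls ended with no filter or without RFP+ 11, RFP+ 3 or RFP- 12. At least 1 ended in each setting with 1 to 3 lower genes (1 with the groups alone). Of the 11 genes of MHC class II presentation, 4 fell over all genes tested, and 9 fell and 1 rose adjusted over the list alone (median log2 -1.25, camera adjusted p = 2.97e-10, adjusted p = 0.13 with an estimated correlation). With the block 6 fell over all genes. The dendritic cell list was lower too (median log2 -0.53, camera adjusted p = 0.00769, adjusted p = 0.132 with an estimated correlation), in 3 of 3 pairs. Ass1, an enzyme of arginine synthesis chosen after its values were seen, fell from 5.47 ± 2.16 to 0.955 ± 0.47 FPKM (log2 -1.70 ± 0.26, limma adjusted p = 0.0249).

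In all, limma placed 15 genes higher and 6 lower in RFP+ cells of B16F10, and 98 and 62 with the library numbers as a block, among them all 21 of the former. After scaling to the macrophage core genes 12 were higher and 15 lower, and after quantile normalization 18 and 3. Without RFP- number 11 there were 51 higher and 39 lower genes, and without RFP- number 12 there were 4 and 0. Most single calls depended on the setting. Of the 21 genes, 4 still passed with the compared groups alone, 4 with no filter and 4 without RFP- number 12.

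Pf4, the gene of the chemokine platelet factor 4 that the series title names, was 1609 ± 472 FPKM in RFP+ and 499 ± 209 FPKM in RFP- cells of B16F10, higher in 3 of 3 pairs. Its log2 difference of 1.74 ± 0.37 did not pass without the block (limma adjusted p = 0.12) and passed with it (SE 0.19, adjusted p = 0.00129). Pf4 (chromosome 5, 90772435 to 90773383, GRCm38) lies between Ppbp (chromosome 5, 90768518 to 90770063) and Cxcl3 (chromosome 5, 90786103 to 90789600), all on the plus strand. With the block, the neutrophil-attracting chemokines Cxcl3 (2.43 ± 0.36) and Cxcl2 (1.44 ± 0.14) and the CC chemokine Ccl8 (1.56 ± 0.17) rose, with limma adjusted p of 0.00821, 0.0006 and 0.00148, against 0.112, 0.426 and 0.275 without it. Ccl17 (-2.61 ± 0.47) and Ccl22 (-1.70 ± 0.32), ligands of the receptor CCR4, fell with the block (limma adjusted p = 0.0226 and 0.0309, against 0.217 and 0.482 without it). Of 21 chemokine genes 1 rose over all genes tested, 6 rose and 5 fell adjusted over the list alone, and 10 rose and 4 fell with the block. The chemokine list rose (median log2 0.67, camera adjusted p = 0.00967, adjusted p = 0.13 with an estimated correlation).

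Of the other focus genes in B16F10, none passed in limma with or without the block. The nitric oxide synthase gene Nos2, which also uses arginine, was 6.24 ± 0.855 against 3.07 ± 0.667 FPKM (log2 0.84 ± 0.24, limma adjusted p = 0.332, and 0.0553 with the block). The mannose receptor Mrc1 (log2 0.68 ± 0.38), Vegfa (0.58 ± 0.30), the PD-L1 gene Cd274 (0.40 ± 0.17) and Il10 (0.76 ± 0.62) had higher means in RFP+ cells. C1qa (-0.48 ± 0.37), Cxcl9 (-0.63 ± 0.22), Tgfb1 (-0.35 ± 0.21), Ccr2 (-0.33 ± 0.41) and Cxcl10 (-0.061 ± 0.35) had lower means, and the sign for Cxcl10 turned under quantile normalization. Their limma adjusted p-values were 0.459 or more, and 0.0681 or more with the block.

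Matrix remodelling and oxidative stress were the lists whose rise in B16F10 was kept with an estimated correlation, though not with the block as well (adjusted p = 0.0739 and 0.0748 in camera). Of 18 matrix remodelling genes 2 rose, Mmp12 and Mmp13, and 5 did adjusted over the list alone (median log2 0.46, camera adjusted p = 2.95e-07, adjusted p = 0.0433 with an estimated correlation). With the block fibronectin (Fn1, log2 1.57 ± 0.12) and thrombospondin 1 (Thbs1, 1.87 ± 0.13) rose as well, with limma adjusted p of 0.000199 and 0.000102 against 0.117 and 0.156 without it, and 6 members in all. Of 15 genes of oxidative stress, heme and iron 0 passed over all genes and 4 rose adjusted over the list alone (median log2 0.32, camera adjusted p = 0.0002, adjusted p = 0.0459 with an estimated correlation). The heme oxygenase gene Hmox1 was 795 ± 244 against 300.0 ± 92.2 FPKM (log2 1.40 ± 0.26, limma adjusted p = 0.0549, and 0.000199 with the block, where it was the 1 member that passed).

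Further lists rose in B16F10 only with the preset correlation. Of 16 lipid-associated macrophage genes 2 rose, Spp1 and Cd36, and 5 rose and 1 fell adjusted over the list alone (median log2 0.41, camera adjusted p = 3.59e-05, adjusted p = 0.16 with an estimated correlation), and 4 rose with the block. Of 24 hypoxia response genes 2 rose, the vasodilator peptide gene Adm (log2 1.60 ± 0.27, limma adjusted p = 0.0431) and the prolyl hydroxylase gene Egln3 (1.16 ± 0.21, adjusted p = 0.0499). Adjusted over the list alone 3 did (median log2 0.32, camera adjusted p = 3.52e-05, adjusted p = 0.353 with an estimated correlation). Of 25 lysosome genes 2 rose, Ctsl and Atp6v0d2, and 2 adjusted over the list alone (median log2 0.073, camera adjusted p = 0.0232, adjusted p = 0.626 with an estimated correlation), though the median was -0.14 without RFP- number 11 (camera adjusted p = 0.997). After scaling to the macrophage core genes, which moved the RFP+ libraries by a log2 of -0.19 against the RFP- libraries, lysosome genes were not called (camera adjusted p = 0.155). Among complement and resident-like genes (median log2 0.51, camera adjusted p = 0.0125, adjusted p = 0.626 with an estimated correlation), 0 of 17 passed without the block and 6 rose with it. Among them were the folate receptor gene Folr2 (2.1998 ± 0.34, limma adjusted p = 0.0103, and 0.0873 without it) and the clotting factor gene F13a1 (1.59 ± 0.22, adjusted p = 0.00549, and 0.498 without it). The type I interferon list (23 genes) rose (median log2 0.38, camera adjusted p = 0.00378, adjusted p = 0.626 with an estimated correlation). The classical activation list (16 genes) rose (median log2 0.31, camera adjusted p = 0.0376, adjusted p = 0.626 with an estimated correlation), as did the monocyte-like list (14 genes, median log2 0.38, camera adjusted p = 0.0232, adjusted p = 0.58 with an estimated correlation). The monocyte-like median turned to -0.45 with array weights. The immune suppression list (18 genes) rose as well (median log2 0.21, camera adjusted p = 0.0376, adjusted p = 0.16 with an estimated correlation). No member of these 4 lists passed over all genes without the block, and 1, 3, 3 and 4 rose with it, while 1 immune suppression gene fell. Adjusted over the list alone, 0, 0, 2 and 2 of their members rose.

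Oxidative phosphorylation fell as a list in B16F10 RFP+ libraries, with 28 of 30 members lower and 0 past the threshold, over all genes or adjusted over the list alone (median log2 -0.24, camera adjusted p = 4.39e-05, adjusted p = 0.58 with an estimated correlation). Melanocytic genes were high in both gates of B16F10, and whether tumour RNA carries or dilutes such list differences was not tested. MHC class I presentation (13 genes, 0 past the threshold and 1 adjusted over the list alone) fell as well (median log2 -0.24, camera adjusted p = 0.0188, adjusted p = 0.495 with an estimated correlation). Glycolysis (18 genes, 0 past the threshold either way) fell without the block (median log2 -0.19, camera adjusted p = 0.0395, adjusted p = 0.58 with an estimated correlation) and not with it (camera adjusted p = 0.0605). The lists of alternative activation, interferon gamma response, arginine and polyamine metabolism, cholesterol synthesis, unfolded protein response, immediate early genes and cell cycle were not called in B16F10, with camera adjusted p of 0.857, 0.881, 0.905, 0.121, 0.638, 0.498 and 0.845. With the block 2 alternative activation genes rose and 2 fell, 1 interferon gamma gene fell, 1 arginine and polyamine gene rose and 1 fell, and 1 immediate early gene rose.

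Of the 15 functional lists called in B16F10, 5 were called by camera in every other setting with the preset correlation: MHC class II, hypoxia response, lipid-associated genes, matrix remodelling and oxidative stress. The hypoxia response median was 0.10 without RFP- number 12, the library that stood apart, 0.14 after scaling to the macrophage core genes, 0.20 with the block without the number 12 pair and 0.52 without RFP- number 11. Without RFP- number 12 the medians were -0.048 for oxidative phosphorylation, -0.077 for glycolysis and -0.11 for MHC class I, and these, classical activation and monocyte-like genes were not called (camera adjusted p = 0.0941, 0.119, 0.085, 0.222 and 0.128). The calls of glycolysis, complement, monocyte-like genes, immune suppression and lysosome ended without RFP- number 11 (camera adjusted p = 0.139, 0.8, 0.368, 0.0527 and 0.997). Without RFP- number 3 those of classical activation, type I interferon, MHC class I, chemokines and immune suppression ended (camera adjusted p = 0.467, 0.0569, 0.0569, 0.0569 and 0.0788). Leaving out RFP+ number 12 ended the calls of glycolysis, complement, immune suppression and lysosome (camera adjusted p = 0.332, 0.305, 0.0735 and 0.33), and the lysosome median turned to -0.035. Without RFP+ number 11 the calls ended for classical activation, type I interferon, MHC class I and immune suppression (camera adjusted p = 0.66, 0.141, 0.101 and 0.101). Without RFP+ number 3 they ended for glycolysis, complement, monocyte-like genes and lysosome (camera adjusted p = 0.0596, 0.0939, 0.29 and 0.089), with a lysosome median of -0.0079. Classical activation was not called with pseudocount 5, no filter, the 5 FPKM filter, quantile normalization or upper-quartile scaling (camera adjusted p = 0.0587, 0.0641, 0.0552, 0.0581 and 0.0562). Glycolysis was not called in 4 of these 5, all but no filter, nor with the groups alone, array weights or core scaling (camera adjusted p from 0.0532 to 0.248), nor with the block without the number 12 pair (0.845). MHC class I was not called with quantile normalization (camera adjusted p = 0.117), and oxidative phosphorylation neither with array weights (0.144) nor with the block without the number 12 pair (0.179). Monocyte-like genes were not called with the 5 FPKM filter, the groups alone or array weights (camera adjusted p = 0.0534, 0.0619 and 0.486). Immune suppression was not called with upper-quartile scaling, the groups alone, core scaling or without MC38 RFP- number 2 (camera adjusted p = 0.0513, 0.0893, 0.0603 and 0.0536). Over the left-out libraries the medians in B16F10 ran from 0.15 to 0.90 for complement, 0.093 to 0.69 for classical activation, 0.21 to 0.56 for type I interferon, 0.031 to 0.85 for monocyte-like genes, 0.42 to 0.93 for chemokines, 0.084 to 0.23 for immune suppression, -0.14 to 0.23 for lysosome and 0.25 to 0.55 for oxidative stress. For lists that fell they ran from -0.33 to -0.048 for oxidative phosphorylation, -0.23 to -0.077 for glycolysis and -0.38 to -0.11 for MHC class I.

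**Figure D1:**
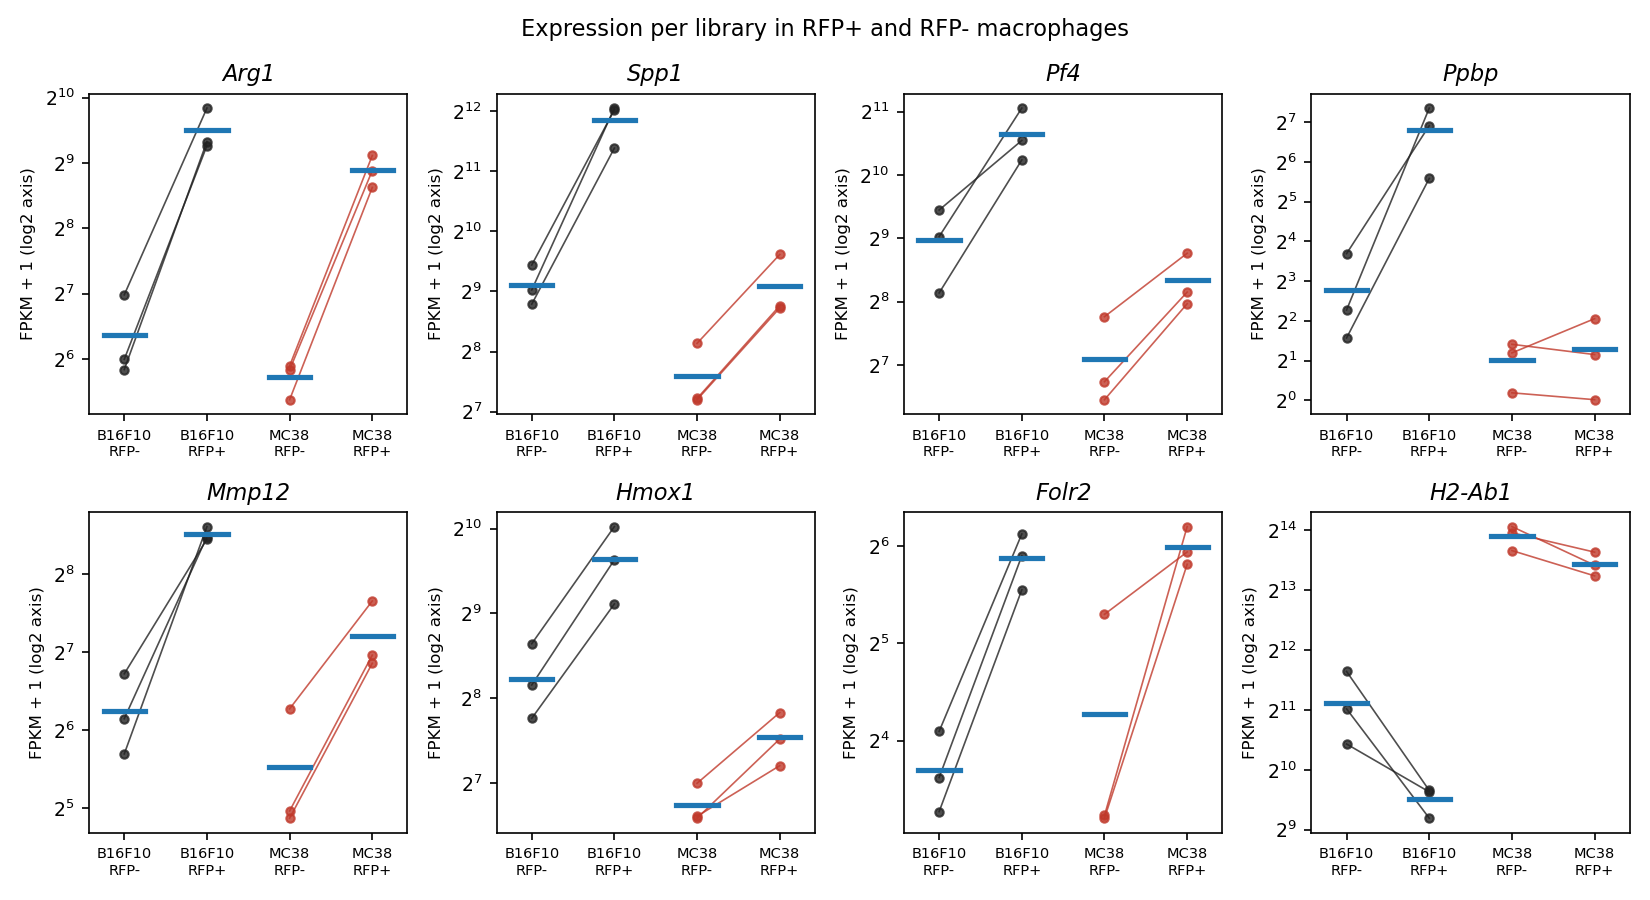
FPKM + 1 on a log2 axis for 8 genes in each of the 12 libraries, by tumour and gate, with points for libraries, lines joining libraries of the same tumour and number, and blue bars for group means. Arg1 averaged 724 FPKM in RFP+ and 81.5 FPKM in RFP- cells of B16F10, and 473 and 51.7 FPKM in MC38, and was higher in the RFP+ library of each of the 6 pairs, as Spp1 and Pf4 were.

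The same question was asked within MC38 tumours. Arg1 was 473 ± 79.7 FPKM in RFP+ and 51.7 ± 9.74 FPKM in RFP- cells (SD, n = 3 each), a log2 difference of 3.17 ± 0.27 (SE, limma adjusted p = 0.000286). The lipid droplet gene Hilpda, induced by low oxygen, rose from 86.6 ± 17 to 229.5 ± 26.6 FPKM (log2 1.41 ± 0.17, limma adjusted p = 0.011). The C-type lectin receptor gene Clec4d rose from 33.4 ± 2.82 to 65.8 ± 2.12 FPKM (log2 0.96 ± 0.12, limma adjusted p = 0.0112). Spp1 was 546 ± 205 against 191 ± 77 FPKM (log2 1.52 ± 0.30) and Pf4 322 ± 98.2 against 136 ± 69.9 FPKM (1.31 ± 0.37). Both passed with the block (limma adjusted p = 0.000553 and 0.0138) and not without it (0.116 and 0.629).

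These 3 genes were the ones higher in MC38 by limma, and 0 were lower. With the block 42 were higher and 10 lower, and after quantile normalization 5 and 1. Scaled to the macrophage core genes, Arg1 was the 1 gene left to pass in limma, while Hilpda (log2 1.28, adjusted p = 0.889) and Clec4d (0.83, adjusted p = 1) kept most of their difference. Among the genes that rose with the block were Mmp12 (1.79 ± 0.20), the fatty acid carrier Fabp5 (1.43 ± 0.16), Folr2 (2.08 ± 0.34), the sphingosine phosphate receptor S1pr1 (1.60 ± 0.22) and Tmeff1 (1.32 ± 0.22), with limma adjusted p of 0.00534, 0.00534, 0.031, 0.0113 and 0.0315, against 0.111, 0.146, 0.146, 0.321 and 0.111 without it. Asb2, the lectin-like receptor genes Klra17 and Klrb1b, and Tmem176a had the smallest p-values among lower genes but did not pass without the block (log2 -1.48, -2.00, -1.48 and -1.33, limma adjusted p = 0.146, 0.111, 0.112 and 0.111). With the block all 4 fell (limma adjusted p = 0.0158, 0.00601, 0.0108 and 0.0315), as did Clec4b1 (-1.44 ± 0.23, adjusted p = 0.0255) and Tmem176b (-1.21 ± 0.17, adjusted p = 0.0113).

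Of the focus genes in MC38, Nos2 rose with the block (log2 1.03 ± 0.18, limma adjusted p = 0.0399, and 0.247 without it), and the others beside Arg1, Spp1 and Pf4 did not pass. Their log2 differences were 0.28 for Mrc1, 0.63 for Vegfa, 0.18 for Cd274, -0.37 for Cxcl9, -0.68 for Ccr2 and -0.46 for H2-Ab1 (limma adjusted p = 1 for each). For C1qa, Cxcl10, Il10 and Tgfb1 the differences were 0.064, 0.084, 0.058 and 0.017.

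The lists that rose in MC38 with either correlation were hypoxia response, matrix remodelling, lipid-associated macrophage genes and oxidative stress. With the block and an estimated correlation matrix remodelling no longer passed in camera (adjusted p = 0.0524). Of 24 hypoxia response genes 1 rose, Hilpda, and 7 did adjusted over the list alone (median log2 0.51, camera adjusted p = 5.23e-22, adjusted p = 0.0338 with an estimated correlation), and 23 had a positive difference. Matrix remodelling (18 genes) rose (median log2 0.32, camera adjusted p = 1.88e-07, adjusted p = 0.0237 with an estimated correlation), and so did the lipid-associated list (16 genes, median log2 0.50, camera adjusted p = 1.36e-10, adjusted p = 0.0385 with an estimated correlation). The list of oxidative stress, heme and iron (15 genes) rose as well (median log2 0.30, camera adjusted p = 1.56e-05, adjusted p = 0.0237 with an estimated correlation). None of their members passed over all genes, and 5, 3 and 3 rose adjusted over the list alone. With the block the matrix gene Adam8 (0.76 ± 0.10, limma adjusted p = 0.0112, and 1 without it) rose. So did the lipid-associated gene Gpnmb (1.11 ± 0.14, adjusted p = 0.00986, and 0.423 without it) and Hmox1 (0.79 ± 0.11, adjusted p = 0.012, and 0.912 without it).

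Glycolysis rose as a list in MC38, with 17 of 18 members higher and 0 past the threshold either way (median log2 0.30, camera adjusted p = 7.59e-08, adjusted p = 0.072 with an estimated correlation). Lysosome genes (25 genes, 2 adjusted over the list alone, median log2 0.19, camera adjusted p = 2.33e-08, adjusted p = 0.231 with an estimated correlation) rose too. So did complement and resident-like genes (17 genes, 2 adjusted over the list alone, median log2 0.25, camera adjusted p = 0.000821, adjusted p = 0.437 with an estimated correlation). Arginine and polyamine metabolism genes (14 genes, 1 adjusted over the list alone, median log2 0.15, camera adjusted p = 0.00644, adjusted p = 0.0557 with an estimated correlation) rose as a list. No member of these 3 lists passed over all genes. In the arginine list the transporter gene Slc7a2 rose with the block (1.36 ± 0.25, limma adjusted p = 0.0483, and 1 without it). MHC class II presentation fell as a list (median log2 -0.45, camera adjusted p = 2.08e-05, adjusted p = 0.245 with an estimated correlation), with 0 of 11 genes past the threshold either way, and so did the dendritic cell list (median log2 -0.40, camera adjusted p = 1.11e-05). With the block camera also called alternative activation (adjusted p = 0.018), classical activation (0.0384), chemokines (0.018), monocyte-like genes (0.00494) and immune suppression (0.00213) higher, and interferon gamma response (0.0247), cholesterol synthesis (0.0245) and cell cycle (0.0266) lower. With an estimated correlation their adjusted p-values in the block fit were 0.114, 0.417, 0.235, 0.263, 0.114, 0.417, 0.365 and 0.461. Members that rose over all genes with the block numbered 4 for hypoxia response, 3 for matrix remodelling, 3 for lipid-associated genes, 3 for complement, 2 for lysosome, 2 for arginine metabolism, 2 for chemokines, and 1 each for oxidative stress, classical activation and monocyte-like genes. The complement list was not called without MC38 RFP- number 1 (camera adjusted p = 0.0732), and its median ran from 0.12 to 0.43 over the left-out libraries. The arginine and polyamine median was 0.075 without MC38 RFP- number 2 and 0.074 without RFP- number 3, that of oxidative stress 0.18 without RFP+ number 1, and that of matrix remodelling 0.50 without RFP+ number 3, all still called by camera. Oxidative phosphorylation, type I interferon, MHC class I, unfolded protein response and immediate early genes were not called in either fit, with camera adjusted p of 0.435, 0.905, 0.498, 0.689 and 0.381 without the block.

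Averaged over both tumours, RFP+ cells had 40 genes higher and 13 lower in limma. Arg1 (log2 3.19 ± 0.19), Spp1 (2.13 ± 0.21), Atp6v0d2 (2.17 ± 0.29), Folr2 (2.14 ± 0.31), Mmp12 (2.05 ± 0.24) and Pf4 (1.53 ± 0.26) rose, with limma adjusted p of 3.69e-06, 0.000504, 0.0052, 0.00941, 0.00195 and 0.0234, each higher in 6 of 6 pairs. The hypoxia genes Adm (1.32 ± 0.19) and Egln3 (1.24 ± 0.15) rose as well (limma adjusted p = 0.0099 and 0.00195, 6 of 6 pairs), though Egln3, at 1.06, did not pass after scaling to the macrophage core genes (limma adjusted p = 0.105). H2-Ab1 (-1.001 ± 0.19), H2-Eb1 (-1.09 ± 0.19), H2-DMb1 (-0.88 ± 0.13), the receptor genes Clec4b1 (-1.42 ± 0.21), Klra17 (-1.47 ± 0.27) and Klrb1b (-1.35 ± 0.20), the nuclease gene Dnase1l3 (-0.85 ± 0.16) and Tmem176a (-1.13 ± 0.18) fell in 6 of 6 pairs, with limma adjusted p from 0.0099 to 0.0443. With the block there were 156 higher and 71 lower genes, and after scaling to the macrophage core genes 17 and 20. The block brought in the acute phase gene Saa3 (1.86 ± 0.21, limma adjusted p = 0.00112, and 0.0661 without it) and S1pr1 (1.35 ± 0.15, adjusted p = 0.00115, and 0.0631 without it). On the lower side it brought in the adaptor gene Sh2d1b1 (-0.91 ± 0.17, adjusted p = 0.0198, and 0.0907 without it).

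By list, 3 of 24 hypoxia response genes rose over all genes and 12 adjusted over the list alone (median log2 0.41, camera adjusted p = 1.70e-15, adjusted p = 0.0626 with an estimated correlation). For matrix remodelling the counts were 3 and 8 of 18 (median log2 0.42, camera adjusted p = 1.40e-10, adjusted p = 0.00963 with an estimated correlation). For oxidative stress, heme and iron they were 2 and 3 of 15 (median log2 0.31, camera adjusted p = 6.90e-07, adjusted p = 0.00963 with an estimated correlation). Hmox1 (log2 1.09 ± 0.18) and the glutathione synthesis gene Gclm (0.70 ± 0.13) rose (limma adjusted p = 0.0194 and 0.0407). Lipid-associated genes rose in 3 and 9 of 16 cases (median log2 0.44, camera adjusted p = 1.40e-10, adjusted p = 0.0548 with an estimated correlation), among them the lipid droplet gene Plin2 (0.50 ± 0.098, limma adjusted p = 0.0474). Of 11 MHC class II genes 4 fell, and 9 fell and 1 rose adjusted over the list alone (median log2 -0.80, camera adjusted p = 3.66e-12, adjusted p = 0.0626 with an estimated correlation), and the dendritic cell list fell with them (median log2 -0.50, camera adjusted p = 5.10e-06). Camera also called classical activation, type I interferon, chemokines, complement and resident-like genes, monocyte-like genes, immune suppression and lysosome higher (adjusted p = 0.0242, 0.0166, 0.0103, 0.000384, 0.0134, 0.0147 and 6.81e-06), and oxidative phosphorylation, MHC class I and cholesterol synthesis lower (0.000299, 0.0242 and 0.0295). With an estimated correlation these had adjusted p-values of 0.567, 0.612, 0.0626, 0.442, 0.442, 0.0626, 0.411, 0.557, 0.442 and 0.567. Glycolysis, with opposite signs in the 2 tumours, was not called (camera adjusted p = 0.199). With the block and an estimated correlation, hypoxia response (adjusted p = 0.0207), type I interferon (0.0417) and lipid-associated genes (0.034) passed in camera beside matrix remodelling and oxidative stress.

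Members that passed over all genes with the block numbered 10 for hypoxia response, 7 for matrix remodelling, 7 for lipid-associated genes, 3 for oxidative stress, 4 for classical activation, 4 for complement, 4 for monocyte-like genes, 4 for lysosome, 2 for alternative activation and 2 for immediate early genes, all higher. Chemokines had 9 higher and 2 lower, immune suppression 4 and 1, and arginine metabolism 2 and 1. MHC class II had 6 lower, interferon gamma response 2 and unfolded protein response 1. Without B16F10 RFP- number 12 the oxidative phosphorylation median was -0.036, and that list, classical activation, type I interferon, MHC class I and monocyte-like genes were not called (camera adjusted p = 0.0709, 0.136, 0.0747, 0.0797 and 0.0709). Over both tumours 8 of 15 lists were called by camera in every other setting with the preset correlation: hypoxia response, MHC class II, chemokines, lipid-associated genes, matrix remodelling, immune suppression, lysosome and oxidative stress. The calls of complement, monocyte-like genes and cholesterol synthesis ended without B16F10 RFP- number 11 (camera adjusted p = 0.12, 0.131 and 0.323). Classical activation, type I interferon and MHC class I ended without B16F10 RFP+ number 11 (camera adjusted p = 0.309, 0.224 and 0.111), and these 3 and cholesterol synthesis without B16F10 RFP- number 3 (0.216, 0.0988, 0.0635 and 0.185). Without MC38 RFP+ number 3 the classical activation median turned to -0.015, and its call and those of type I interferon, monocyte-like genes and cholesterol synthesis ended (camera adjusted p = 0.328, 0.673, 0.105 and 0.105). Without MC38 RFP- number 1 classical activation, type I interferon and cholesterol synthesis were not called (camera adjusted p = 0.172, 0.291 and 0.437), nor type I interferon without MC38 RFP- number 2 (0.133). Cholesterol synthesis was not called with the 5 FPKM filter, quantile normalization or core scaling, nor without B16F10 RFP+ number 12 or MC38 RFP+ number 2 (camera adjusted p = 0.0753, 0.0701, 0.139, 0.261 and 0.0539). MHC class I was not called with quantile normalization or without MC38 RFP+ number 1 or RFP- number 3 (camera adjusted p = 0.0666, 0.0516 and 0.0502). Monocyte-like genes were not called without B16F10 RFP+ number 3 (camera adjusted p = 0.099) or with array weights (median log2 -0.026, 0.803). Oxidative phosphorylation was not called with array weights or with the block without the number 12 pair (camera adjusted p = 0.0731 and 0.0777). Over the left-out libraries the medians over both tumours ran from -0.015 to 0.37 for classical activation, 0.07 to 0.34 for type I interferon, -0.12 to -0.031 for MHC class I, 0.098 to 0.46 for chemokines, 0.17 to 0.57 for monocyte-like genes, 0.12 to 0.27 for immune suppression, 0.058 to 0.22 for lysosome, -0.20 to -0.023 for cholesterol synthesis and -0.19 to -0.036 for oxidative phosphorylation.

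Whether the tumours shared a response was asked from the overlap of genes that passed, without Arg1. Each gene had 1 variance for both tumours, which may raise the overlap by itself. Without the block the 1 other gene higher in both was Clec4d, of 14 and 2 genes (unadjusted Fisher's exact p = 0.00237 across genes, which are not independent replicates). With the block, 23 genes were higher in both where independence gives 0.337 (unadjusted Fisher's exact p = 1.18e-38), among them Spp1, Pf4, Mmp12, Folr2, Hmox1, Ctsl, Fn1 and Hilpda. On the lower side Clec4b1 and Klrb1b fell in both with the block, where independence gives 0.0525 (unadjusted Fisher's exact p = 0.00119). Across all 11808 genes, again not independent, the log2 differences of the tumours had r = 0.234.

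**Figure D2:**
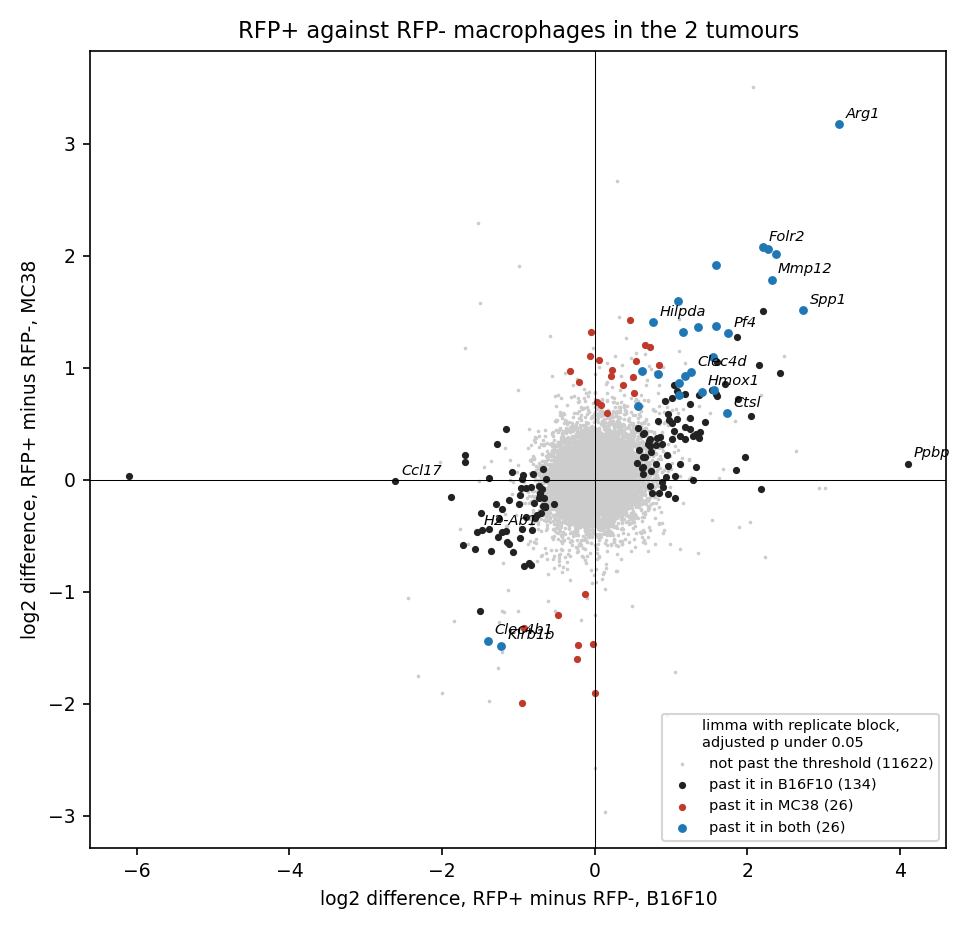
Log2 difference, RFP+ minus RFP-, in B16F10 (x axis) and in MC38 (y axis) for the 11808 genes kept, 1 point per gene, coloured by adjusted p under 0.05 with the block. Of these genes 134 passed in B16F10 alone, 26 in MC38 alone and 26 in both, with Arg1 at 3.21 and 3.17.

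Whether the RFP+ and RFP- cells differed by tumour was tested directly, as the difference in B16F10 minus that in MC38. No gene passed in limma, with 455 genes at an unadjusted p under 0.05 where chance gives 590.4. With the block 4 passed: Ppbp (log2 3.96 ± 0.46, SE), Ctsl (1.14 ± 0.15), Ass1 (-1.86 ± 0.24) and the small nucleolar RNA gene Snord15b (1.90 ± 0.24), each with a limma adjusted p of 0.0332, against 0.895 without it. Snord15b was chosen after its values were seen and was listed at 0 in all 6 B16F10 libraries. Ppbp was 1.47 ± 1.59 against 1.03 ± 0.792 FPKM in MC38, and Ctsl 245 ± 42.2 against 162 ± 29.3 FPKM. Ass1 was 17.1 ± 1.91 against 15.3 ± 2.88 FPKM in MC38.

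By list, the RFP+ minus RFP- difference was lower in B16F10 for glycolysis (18 genes, median log2 -0.41, camera adjusted p = 2.46e-06, adjusted p = 0.536 with an estimated correlation). It was lower for oxidative phosphorylation (30 genes, median log2 -0.25, camera adjusted p = 0.00441, adjusted p = 0.753 with an estimated correlation), and for MHC class II (11 genes, median log2 -0.87, camera adjusted p = 5.83e-05, adjusted p = 0.536 with an estimated correlation). It was higher for type I interferon response (23 genes, median log2 0.29, camera adjusted p = 0.0234, adjusted p = 0.753 with an estimated correlation). No member passed over all genes, and 1, 0, 6 and 0 did adjusted over the list alone. Without B16F10 RFP- number 12 the oxidative phosphorylation median was -0.044 and its call ended, as did that of type I interferon (camera adjusted p = 0.64 and 0.0847). The type I interferon median turned to -0.061 without MC38 RFP- number 3 (camera adjusted p = 0.938). Its call ended without MC38 RFP+ number 1 or 2, or B16F10 RFP+ number 11 or RFP- number 3 as well (camera adjusted p = 0.366, 0.145, 0.303 and 0.18), and with pseudocount 5 or no filter (0.104 and 0.0543). Oxidative phosphorylation was not called with quantile normalization, array weights or the block without the number 12 pair, nor without MC38 RFP- number 3 (camera adjusted p = 0.455, 0.7, 0.802 and 0.124). Over the left-out libraries the medians ran from -0.061 to 0.57 for type I interferon, -0.36 to -0.044 for oxidative phosphorylation and -1.17 to -0.54 for MHC class II. Glycolysis and MHC class II were called by camera in every other setting with the preset correlation, glycolysis also without RFP- number 12 (median log2 -0.32, camera adjusted p = 2.76e-08). With the block Ppbp of the chemokine list, Ctsl of the lysosome list and Ass1 of the arginine list passed, and camera also called hypoxia response (adjusted p = 0.0165) and MHC class I (0.0444) lower, and classical activation (0.0444), chemokines (0.000409), monocyte-like genes (0.0444) and matrix remodelling (0.00388) higher. None of these 10 was called with an estimated correlation in the block fit, where the adjusted p-values were 0.199 or more.

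The test fry asks whether the genes of a list move one way on balance, without comparing them with other genes, and called 5 of the 15 lists that camera called in B16F10. These were MHC class II, chemokines, matrix remodelling, immune suppression and oxidative stress (limma fry adjusted p = 0.0186, 0.0349, 0.00977, 0.0349 and 0.00977). For hypoxia response, lipid-associated genes, oxidative phosphorylation, type I interferon and lysosome the fry adjusted p-values in limma were 0.221, 0.0586, 0.336, 0.605 and 0.595. For complement, classical activation, monocyte-like genes, MHC class I and glycolysis they were 0.605, 0.605, 0.546, 0.23 and 0.336. In MC38 fry called 4 of 9: hypoxia response, matrix remodelling, arginine and polyamine metabolism and oxidative stress (limma fry adjusted p = 0.0434, 0.0434, 0.00958 and 0.0259). It did not call MHC class II, glycolysis, lipid-associated genes, complement or lysosome there (limma fry adjusted p = 0.45, 0.0696, 0.0696, 0.687 and 0.361). Over both tumours it called 7 of 15, namely hypoxia response, MHC class II, chemokines, lipid-associated genes, matrix remodelling, immune suppression and oxidative stress (limma fry adjusted p = 0.0136, 0.0136, 0.0297, 0.0136, 0.00231, 0.0136 and 0.00231), and arginine and polyamine metabolism (0.026), which camera did not. In the difference between tumours it called 0 of 4, and arginine and polyamine metabolism, lower, which camera did not (limma fry adjusted p = 0.0389). Between tumours it called all 16 lists that camera called.

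**Figure D3:**
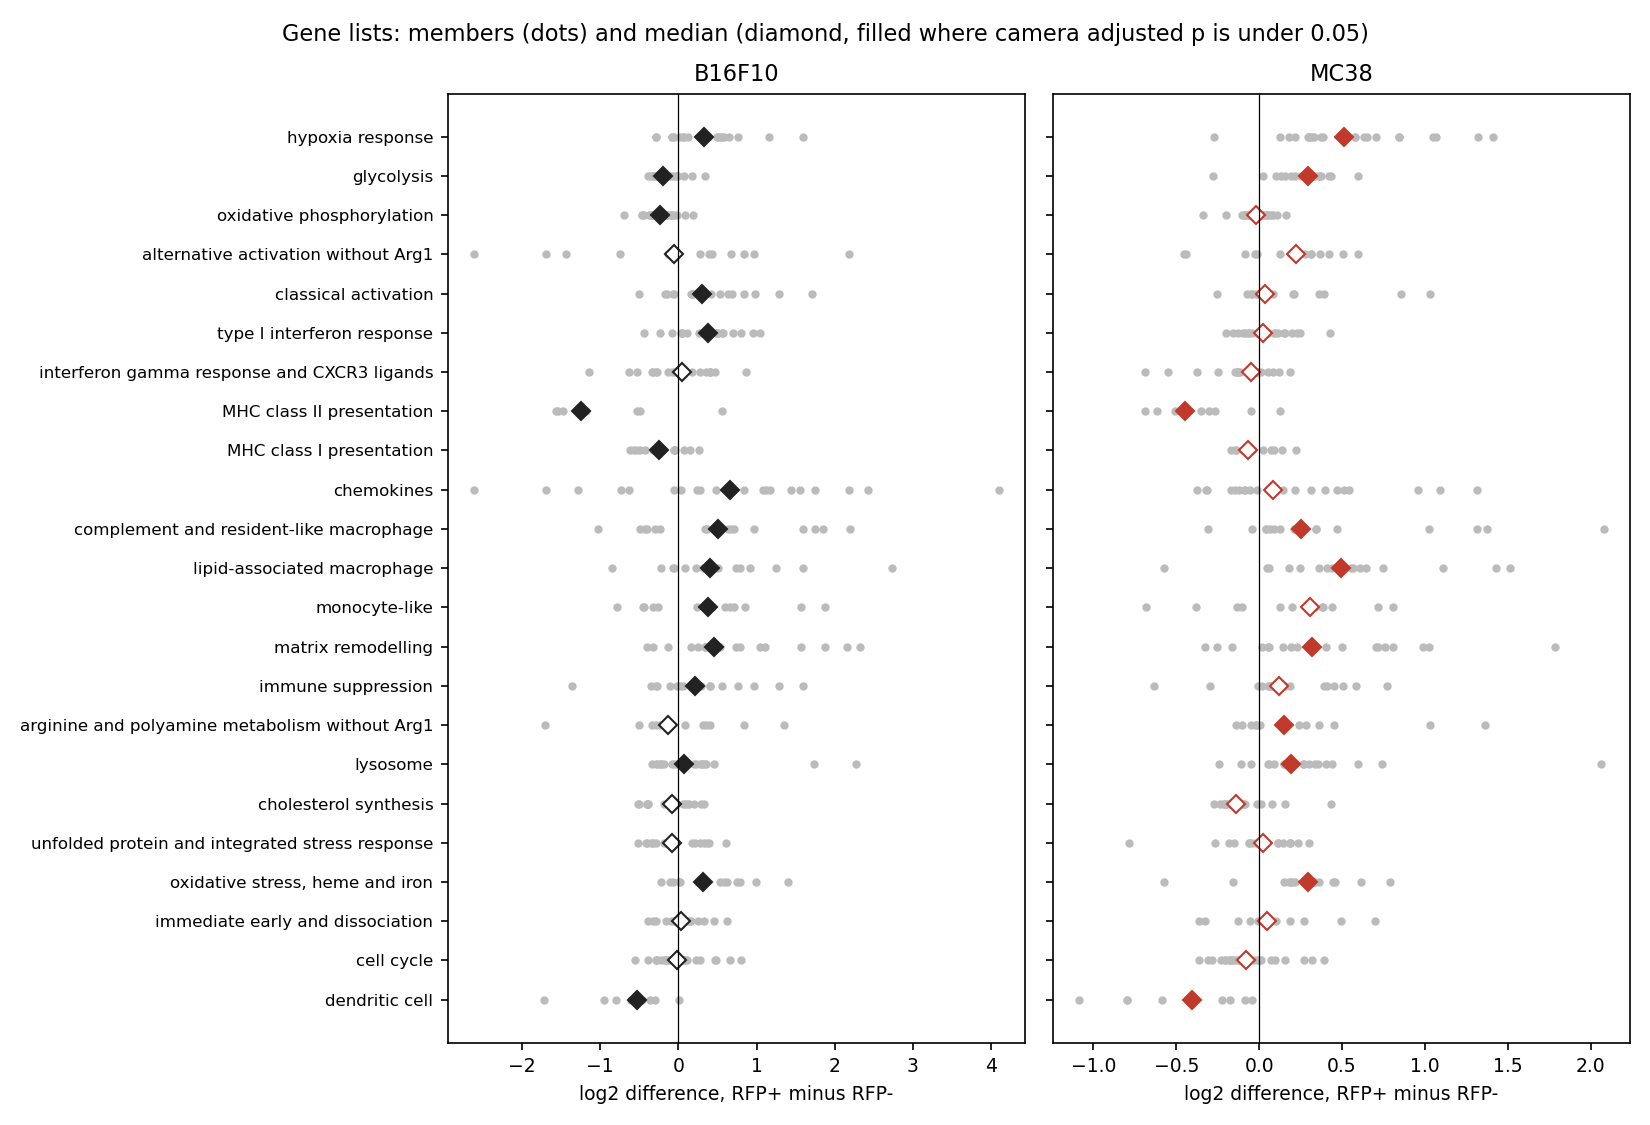
Log2 difference, RFP+ minus RFP-, of each member (dots) and the median (diamonds, filled where the camera adjusted p was under 0.05 with the preset correlation) of 22 functional lists and the dendritic cell list, in B16F10 and in MC38. The MHC class II median was -1.25 in B16F10 and -0.45 in MC38, and the glycolysis median -0.19 and 0.30.

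The last comparison set the B16F10 against the MC38 libraries over both gates. The highest differences were pigment cell genes: Pmel, a melanosome matrix protein, was 1933 ± 330.4 and 2491 ± 514 FPKM in B16F10 RFP+ and RFP- cells against 1.59 ± 0.749 and 1.73 ± 0.733 FPKM in MC38 (log2 9.71 ± 0.17, limma adjusted p = 8.73e-14). Dct (9.74 ± 0.15), Tyrp1 (9.63 ± 0.15), Mlana (9.34 ± 0.17), Slc45a2 (8.25 ± 0.11), Slc24a5 (7.35 ± 0.12), the prostaglandin synthase gene Ptgds (9.35 ± 0.13) and the carbonic anhydrase gene Car14 (7.38 ± 0.14) were higher as well. Their limma adjusted p was 1.57e-13 or less. Lower in B16F10 were Cd34 (-5.50 ± 0.17), the matrix proteoglycan gene Dcn (-5.07 ± 0.13), the interferon-induced GTPase gene Gbp2b (-4.90 ± 0.21), the protease gene Htra1 (-4.84 ± 0.26), Rhox5 (-4.65 ± 0.18), AW112010 (-4.62 ± 0.17), Irg1, the itaconate-forming enzyme (-4.47 ± 0.39), and Ly6a (-4.27 ± 0.15), with limma adjusted p of 2.94e-07 or less. All of these kept their direction and passed after scaling to the macrophage core genes. Whether the genes lower in B16F10 were transcribed by macrophages was not tested, and the fibroblast list was lower there too (median log2 -2.81).

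By limma 5200 genes were higher and 2998 lower in B16F10 (63.4% higher), with a median difference over all genes of 0.23. Scaled to the macrophage core genes the counts were 10231 and 496 (95.4% higher) with a median of 1.83, and after quantile normalization 4208 and 3809 (52.5% higher).

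Interferon and antigen presentation genes were lower in B16F10 libraries, in which the macrophage core list was lower (median log2 -2.05, camera adjusted p = 2.00e-08) and the melanocytic list higher (6.64, adjusted p = 7.64e-10). All 23 type I interferon genes fell over all genes and adjusted over the list alone (median log2 -2.74, camera adjusted p = 2.89e-13, adjusted p = 0.149 with an estimated correlation), such as Irf7 (log2 -4.02 ± 0.24). All 21 interferon gamma genes fell by both adjustments (median log2 -2.61, camera adjusted p = 2.48e-14, adjusted p = 0.013 with an estimated correlation), such as Gbp2 (-3.41 ± 0.15) and Irf1 (-3.05 ± 0.12). All 11 MHC class II genes did (median log2 -2.76, camera adjusted p = 4.94e-08, adjusted p = 0.127 with an estimated correlation), such as Cd74 (-3.23 ± 0.18). Of 18 immune suppression genes 17 fell by both adjustments (median log2 -1.97, camera adjusted p = 3.29e-08, adjusted p = 0.00514 with an estimated correlation), such as the TIM-3 gene Havcr2 (-3.45 ± 0.099) and Cd274 (-2.13 ± 0.12). Classical activation fell in 14 of 16 genes (median log2 -2.50, camera adjusted p = 2.07e-07, adjusted p = 0.149 with an estimated correlation). MHC class I genes fell in 12 of 13 (median log2 -1.85, camera adjusted p = 5.16e-08, adjusted p = 0.0967 with an estimated correlation), again by both adjustments. Immediate early genes fell in 13 of 14 (median log2 -1.60, camera adjusted p = 1.03e-06, adjusted p = 0.127 with an estimated correlation), such as Egr1 (-2.85 ± 0.19). The genes named here had limma adjusted p of 2.28e-08 or less. Scaling to the macrophage core genes moved the B16F10 libraries up by a log2 of 1.92 against the MC38 libraries, so that smaller falls turned sign by the scaling alone. After it the medians were -0.94 for type I interferon, -1.02 for interferon gamma, -1.02 for MHC class II, -0.71 for classical activation, -0.20 for immune suppression, 0.065 for MHC class I and 0.31 for immediate early genes, and camera still called each lower than other genes. Cd274 (log2 -0.26) no longer passed (limma adjusted p = 0.298).

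Energy and division genes were higher in B16F10 libraries, as were the melanocytic genes. All 30 oxidative phosphorylation genes rose (median log2 1.08, camera adjusted p = 3.29e-08, adjusted p = 0.289 with an estimated correlation), such as Ndufa4 (log2 3.47 ± 0.12) and Cycs (1.85 ± 0.11). Of 18 glycolysis genes 15 rose and 3 fell (median log2 1.44, camera adjusted p = 0.00241, adjusted p = 0.281 with an estimated correlation), with Pgk1 at 2.07 ± 0.11. Hypoxia response rose in 19 of 24 genes and fell in 1 (median log2 1.21, camera adjusted p = 0.000931, adjusted p = 0.343 with an estimated correlation). Cholesterol synthesis rose in 16 of 19 (median log2 0.82, camera adjusted p = 0.00241, adjusted p = 0.359 with an estimated correlation). Cell cycle rose in 27 and fell in 1 of 29 (median log2 1.03, camera adjusted p = 8.20e-06, adjusted p = 0.127 with an estimated correlation). Adjusted over the lists alone these counts were 30, 15, 19, 16 and 27 higher. Among the mixed lists, monocyte-like genes fell in 9 and rose in 2 of 14 (median log2 -1.32, camera adjusted p = 0.00559, adjusted p = 0.343 with an estimated correlation). Matrix remodelling genes fell in 13 and rose in 3 of 18 (median log2 -0.84, camera adjusted p = 0.000604, adjusted p = 0.101 with an estimated correlation). Chemokines fell in 8 and rose in 5 of 21 (median log2 -0.48, camera adjusted p = 0.0266, adjusted p = 0.127 with an estimated correlation). Lysosome genes fell in 14 and rose in 5 of 25 (median log2 -0.39, camera adjusted p = 0.00448, adjusted p = 0.453 with an estimated correlation). After scaling to the macrophage core genes the lysosome list was not called (camera adjusted p = 0.411). Without MC38 RFP- number 2 the chemokine median was -0.25, and its call ended with quantile normalization and upper-quartile scaling (camera adjusted p = 0.0898 and 0.0507). Alternative activation, complement, lipid-associated, arginine, unfolded protein response and oxidative stress lists were not called (camera adjusted p = 0.072, 0.0809, 0.952, 0.357, 0.655 and 0.872).

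Markers of cell types other than macrophages moved with the tumours and with the gates. All 13 melanocytic genes were higher in B16F10 (median log2 6.64, camera adjusted p = 7.64e-10, adjusted p = 0.0495 with an estimated correlation). Their mean log2(FPKM + 1) was 7.67 ± 0.282 in RFP+ and 7.56 ± 0.208 in RFP- cells against 0.941 ± 0.201 and 0.816 ± 0.123 in MC38 (SD, n = 3). All 14 macrophage core genes were lower (median log2 -2.05, camera adjusted p = 2.00e-08, adjusted p = 0.106 with an estimated correlation), with means of 7.51 ± 0.336 and 7.32 ± 0.448 against 9.39 ± 0.097 and 9.27 ± 0.0591. Of 6 fibroblast genes 5 were lower and 1 higher in B16F10 (median log2 -2.81, camera adjusted p = 0.000818, adjusted p = 0.0495 with an estimated correlation). Neutrophil and dendritic cell genes were not called between tumours (camera adjusted p = 0.66 and 0.0556).

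Between the gates, the 8 dendritic cell genes fell as a list in RFP+ cells of B16F10 (median log2 -0.53, camera adjusted p = 0.00769, adjusted p = 0.132 with an estimated correlation). The list fell in MC38 (median log2 -0.40, camera adjusted p = 1.11e-05, adjusted p = 0.0182 with an estimated correlation) and over both tumours (median log2 -0.50, camera adjusted p = 5.10e-06, adjusted p = 0.0152 with an estimated correlation). With the block and an estimated correlation it passed in neither (camera adjusted p = 0.107 and 0.0827). The chemokine receptor gene Xcr1 fell over both tumours (log2 -0.85 ± 0.15, limma adjusted p = 0.031, and log2 -0.93 with adjusted p = 0.0737 after scaling to the macrophage core genes). Ccr7 did with the block (-1.15 ± 0.16, adjusted p = 0.00462, and 0.698 without it). Macrophage core, melanocytic, neutrophil and fibroblast lists were not called between the gates without the block, with camera adjusted p of 0.262, 0.988, 0.262 and 0.907 in B16F10 and 0.403, 0.291, 0.943 and 0.422 in MC38. With the block the neutrophil list fell in B16F10 (camera adjusted p = 0.0154, and 0.452 with an estimated correlation), where Il1r2 and Retnlg fell and Mmp8 rose. With the block the RFP+ minus RFP- difference of this list was also lower in B16F10 than in MC38 (camera adjusted p = 0.0266, and 0.767 with an estimated correlation). The macrophage core list rose over both tumours with the block (camera adjusted p = 0.0234, and 0.496 with an estimated correlation), such as Lyz2 (log2 0.68 ± 0.13, limma adjusted p = 0.0211), with 3 members past the threshold over both tumours and 2 in B16F10. With the block 1 melanocytic and 1 T cell gene rose in B16F10 and as many over both tumours. The T cell, NK cell, B cell, endothelial, platelet and epithelial lists had 4, 4, 3, 3, 3 and 1 genes kept, too few for the test. Their median differences were -0.11, -0.35, -0.35, -0.14, -0.33 and 0.17 in B16F10 and 0.044, -0.28, -0.17, -0.072, 0.039 and -0.027 in MC38.

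**Figure D4:**
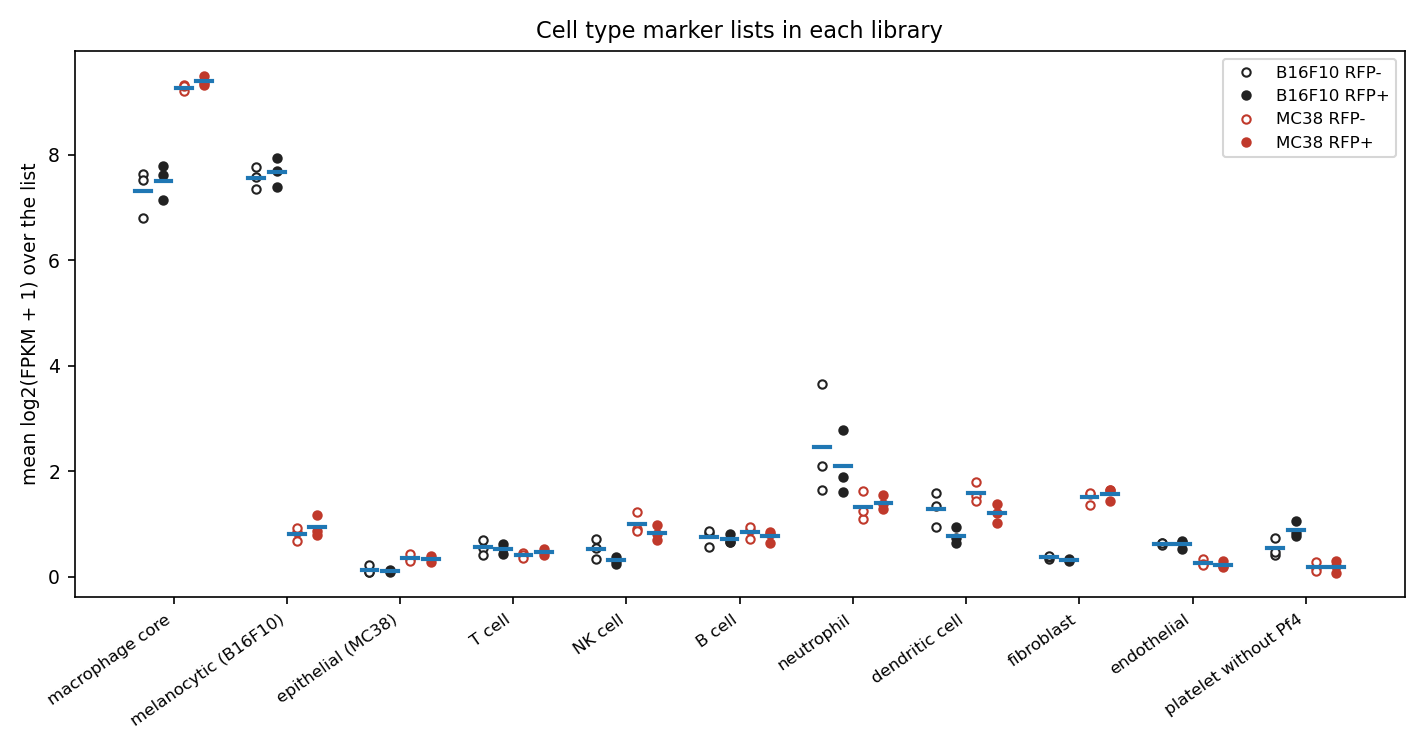
Mean log2(FPKM + 1) of the listed genes of 11 cell types in each of the 12 libraries, by tumour and gate, with points for libraries and a blue bar for the group mean. The melanocytic mean was 7.67 ± 0.282 (SD) in B16F10 RFP+ and 0.941 ± 0.201 in MC38 RFP+ cells, and the dendritic cell mean was 0.771 ± 0.155 in RFP+ and 1.29 ± 0.323 in RFP- cells of B16F10.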

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

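The tests behind the explanations below were chosen after the results were seen, apart from the splits without the block, which were planned, except those over both tumours and between tumours that keep the number of parted pairs.

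In the difference between tumours, the median log2 difference was -0.41 for glycolysis, -0.25 for oxidative phosphorylation, 0.29 for type I interferon response and -0.87 for MHC class II. With the block, Ass1 had a log2 difference of -1.86 ± 0.24, Ctsl 1.14 ± 0.15, Ppbp 3.96 ± 0.46 and Snord15b 1.90 ± 0.24 (limma adjusted p = 0.0332 for each). Without the B16F10 number 12 pair their limma adjusted p-values were 0.0438, 0.00711, 0.0547 and 0.0512.

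Melanocytic transcripts were high and macrophage core genes lower in the B16F10 libraries. RNA of B16F10 tumour cells is a candidate explanation, and the cell cycle list, with a median of 1.03, fits it, although the CD45+ gate would remove tumour cells. None of the 13 melanocytic genes stands in another list, and 3 of the 14 macrophage core genes do. Lower B16F10 depth was not tested by the value of 1 read (log2 ratio up to 1.86), as FPKM is scaled to library size. The melanocytic median was 6.64, its smallest member 2.61. Tumour RNA taken up by macrophages was not tested. Nor was it tested whether tumour RNA carries part of the list differences between the gates in B16F10 or between the tumours.

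Ppbp, and with the block Pf4, rose in RFP+ libraries of B16F10. Platelets stuck to macrophages may carry both RNAs, and no gate is dedicated to their removal. Among 11 other platelet genes the largest rise was 0.436 FPKM (Gp9) and the highest RFP+ mean 1.79 FPKM (Itgb3), against a rise of 103 FPKM for Ppbp and 1111 FPKM for Pf4. The bound, 0.1 of the Ppbp rise, was set after these values were seen. In B16F10 the other genes were too low to exclude platelet RNA: Gp9 rose from 0.179 to 0.616 FPKM, and Clec1b fell from 1.05 to 0.549 FPKM. In MC38 Pf4 passed with the block and Ppbp did not, which argues against platelets as the source of Pf4 there. The CXC chemokine genes beside Pf4 passed with the block, at log2 differences of 2.43 for Cxcl3, 1.12 for Cxcl1 and 1.44 for Cxcl2, values that were seen before they were chosen and test no explanation. Their neighbours Areg (1.14), Mthfd2l (0.65) and Ankrd17 (0.17) did not pass.

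MHC class II genes fell in RFP+ libraries of B16F10. Dendritic cells in the RFP- gate are a candidate explanation. The mean of the dendritic cell list was lower in the RFP+ library of 6 of 6 pairs (log2 differences -0.209, -0.399 and -0.956 in B16F10 and -0.318, -0.402 and -0.408 in MC38). The fall of this list was seen before it was chosen here, so it tests no explanation. Its medians were -0.53 in B16F10 and -0.40 in MC38, where those of MHC class II were -1.25 and -0.45. No gate is dedicated to the removal of dendritic cells, but F4/80 and CD11b are required, and none of the dendritic cell genes stands in another list. Ccr7, the most abundant of these in B16F10 RFP- libraries (17.4 FPKM, against 4.22 in RFP+), rested on number 11 (39.6 FPKM, against 8.44 and 4.03), and with the block and an estimated correlation the list was not called (camera adjusted p = 0.238 in B16F10, 0.107 in MC38 and 0.0827 over both). A lower share of macrophage RNA in the RFP+ libraries would lower the macrophage core genes as well. Their median log2 difference was 0.087, with 5 of 14 lower, which argues against it. Scaling to these genes was no separate test. It moved the RFP+ libraries by a log2 of -0.19 and so could only deepen the fall, to a median of -1.44. Camera compares a list with other genes, so its adjusted p after the scaling (7.73e-11) adds little.

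Exchanging the groups tested whether a chance split of the libraries gives as many genes. Over both tumours, among splits that part all 6 pairs as the real one does, 1 of 32 reached 53 without the block (highest other 2) and 1 of 32 reached 227 with it (highest other 5). The real split thus called more genes than any other. A share of 1 of 32 is the smallest these splits can give, and they were chosen after the results were seen. The counts include Arg1, which the gate reads out. The seeded splits planned at first part other numbers of pairs, and 1 of 100 reached 53 over both tumours (highest other 2) and 1 of 100 reached 8198 between tumours (highest other 2329). With whole pairs, 1 of 10 reached 8198 between tumours (highest other 1). The splits of comparable kind are too few to reach 0.05 between tumours, within a tumour or for the difference between tumours. In B16F10 2 of 10 reached 21, the highest other being 24. That other split set RFP+ 12, RFP+ 3 and RFP- 3 against the rest and parts 1 pair where the real one parts 3, and among splits that part 3 pairs the highest other gave 1. In MC38 1 of 10 reached 3 (highest other 0). With the block 1 of 4 reached 160 in B16F10 (highest other 1) and 1 of 4 reached 52 in MC38 (highest other 0). For the difference between tumours 10 of 10 reached 0 (highest other 1), and with the block 1 of 10 reached 4 (highest other 1).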

How the results depend on the processing

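The scaling of each library to its macrophage core genes, redefined once after its output was seen, the block without the B16F10 number 12 pair, the overlap without Arg1, and the naming rule for the block fit were chosen after seeing the data, and the other settings were planned. Of 5261 gene values under other settings 4666 were the same, 299 weaker, 270 stronger and 26 reversed. Of 1349 functional list values 1196 were the same, 150 weaker and 3 reversed, and all 11 cell type list values, from pseudocount 0.1 and the core scaling alone, were the same, leaving out the macrophage core list scaled to itself. For moved and reversed results the cause was not tested. Camera with the random block was not run.

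Counts are given as higher and lower genes by limma. In B16F10 (15 and 6) they were 6 higher with pseudocount 0.1, 7 and 0 with no filter, 3 lower with quantile normalization, 4 and 1 with the compared groups alone, 128 and 110 with array weights, 98 and 62 with the block, 98 and 65 with the block without the number 12 pair, and 15 lower with core scaling. In MC38 (3 and 0) they were 8 and 3 with pseudocount 5, 5 and 1 with quantile normalization, 7 and 1 with the groups alone, 43 and 16 with array weights, 42 and 10 with the block, 113 and 24 without the number 12 pair, and 1 higher with core scaling. Over both tumours (40 and 13) they were 8 lower with pseudocount 0.1, 13 and 0 with no filter, 166 and 99 with array weights, 156 and 71 with the block, 215 and 112 without the number 12 pair, 17 and 20 with core scaling, and 22 and 6 at a log2 difference of at least 1. For the difference between tumours (0) there were 2 genes with no filter, 4 with the block and 7 without the number 12 pair. Between tumours (5200 and 2998) the counts were 10231 and 496 with core scaling, 4880 and 2823 with the random block, and 2205 and 1484 at a log2 difference of at least 1.

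Of the functional lists called in B16F10, MC38, over both tumours, in the difference and between tumours (15, 9, 15, 4 and 16), 2, 4, 2, 0 and 2 were called with an estimated correlation. With the block 17 were called in MC38 and 10 in the difference, 17 and 9 without the number 12 pair, and 16 and 7 with core scaling. With the block and an estimated correlation 0, 3, 5 and 0 were called in B16F10, MC38, over both tumours and in the difference. Beside the list calls given with the results, with either correlation, the block changed no other. Core scaling moves all genes of a library alike, and so turns the sign of small differences by itself. It moved the median log2 difference over all genes to -0.18 in B16F10, -0.13 over both tumours, -0.10 in the difference and 1.83 between tumours. With the preset correlation, 5, 8, 8, 2 and 14 of these lists were called in every other setting. Where a list was still called, its median was over 1.5 times larger in 16, 3, 12, 5 and 5 values and smaller by as much in 19, 10, 25, 1 and 9.

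Leaving out each library in turn, B16F10 gave 4 to 51 higher, 0 to 39 lower genes and 10 to 15 lists. Higher genes were 4 without B16F10 RFP- 12, 51 without RFP- 11, 6 without each of its RFP+ 12, 11 and 3, and 8 without each of MC38 RFP+ 1, 2 and 3 and RFP- 1 and 3. Lower genes were 39 without B16F10 RFP- 11, 1 without RFP+ 12, RFP- 3, MC38 RFP+ 1 or MC38 RFP- 1, 0 without RFP+ 11, RFP+ 3 or RFP- 12, 2 without MC38 RFP+ 3 or RFP- 2, and 3 without MC38 RFP+ 2 or RFP- 3. MC38 gave 1 to 5 higher genes (1 without MC38 RFP+ 2 or RFP- 1, 5 without RFP- 2), 0 to 4 lower (4 without MC38 RFP+ 3, 1 without MC38 RFP+ 2 or B16F10 RFP- 3) and 8 to 16 lists (16 without MC38 RFP+ 1 or RFP- 3, 14 without RFP- 2). Both tumours gave 16 to 51 higher genes (B16F10 RFP+ 12 25, RFP+ 3 23, MC38 RFP+ 1 16, RFP+ 2 16, RFP- 1 22, RFP- 3 19), 3 to 29 lower (B16F10 RFP+ 12 6, RFP+ 3 6, RFP- 12 7, RFP- 11 29, RFP- 3 7, MC38 RFP+ 1 3, RFP+ 2 5, RFP- 1 6, RFP- 2 6, RFP- 3 7) and 11 to 15 lists. The difference gave 0 to 1 genes (1 without B16F10 RFP- 11 or MC38 RFP+ 2) and 2 to 7 lists (7 without B16F10 RFP- 11, MC38 RFP+ 3 or MC38 RFP- 1, and 2 without MC38 RFP- 3). Between tumours there were 4967 to 5396 higher, 2863 to 3091 lower genes and 16 to 17 lists. The correlation across genes, which are not independent replicates, was r = 0.234, with 0.158 to 0.300 over the left-out libraries (SD 0.0341), 0.300 without B16F10 RFP- 12, 0.158 without B16F10 RFP- 3, 0.199 without MC38 RFP+ 2 and 0.191 without MC38 RFP- 2, and 0.193 with pseudocount 0.1.

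These log2 values turned sign, a list median also where camera, which compares a list with other genes, kept its direction. In B16F10 the monocyte-like median was -0.45 with array weights, the lysosome median -0.14 without RFP- 11, -0.035 without RFP+ 12, -0.0079 without RFP+ 3 and -0.11 with core scaling, Ccr2 0.26 without RFP- 3, and Cxcl10 0.029 with quantile normalization, 0.44 with array weights, 0.26 without RFP+ 3 and 0.25 without RFP- 11. In MC38 C1qa was -0.034 with quantile normalization and -0.055 with core scaling, Cxcl10 -0.16 without RFP+ 3, -0.064 without RFP- 2 and -0.035 with core scaling, Il10 -0.23 without RFP+ 3, -0.12 without RFP- 1 and -0.048 with core scaling, and Tgfb1 -0.0034 with array weights, -0.002 without RFP+ 1, -0.073 without RFP+ 3, -0.10 without RFP- 2 and -0.063 with core scaling. Over both tumours the median was -0.015 for classical activation without MC38 RFP+ 3, -0.026 for monocyte-like genes with array weights and -0.018 for lysosome with core scaling, and in the difference -0.061 for type I interferon without MC38 RFP- 3. Between tumours, core scaling gave medians of 1.52 for lysosome, 0.51 for monocyte-like genes, 0.58 for matrix remodelling, 1.42 for chemokines, 0.31 for immediate early genes and 0.065 for MHC class I, and 0.035 for Dusp1, 0.26 for Ier2, 0.11 for Junb, 0.76 for Lamp2, 0.58 for Lilrb4a, 0.36 for Mmp14, 0.59 for Npc2 and 0.16 for Psmb9, which had fallen.

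The range over left-out libraries was 0.031 to 0.85 for the monocyte-like and -0.14 to 0.23 for the lysosome median in B16F10, -0.68 to 0.26 for Ccr2 and -0.42 to 0.26 for Cxcl10. In MC38 it was -0.16 to 0.28 for Cxcl10, -0.23 to 0.25 for Il10, 0.0092 to 0.10 for C1qa and -0.10 to 0.15 for Tgfb1.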

Other observations

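The values below were chosen after they were seen. With the block, genes of the Clec4 receptor family moved both ways in RFP+ cells of B16F10: Clec4d (1.27 ± 0.13), Clec4n (0.57 ± 0.11) and Clec4e (0.85 ± 0.13) rose and Clec4b1 (-1.40 ± 0.23) and Clec4a1 (-0.65 ± 0.13) fell, with limma adjusted p of 0.000875, 0.0317, 0.00825, 0.0136 and 0.0349 (SE, n = 3 pairs). Clec4a3 (-0.56 ± 0.13) did not pass (limma adjusted p = 0.0728). How reads shared by these paralogs were assigned is not given in the sources used here.

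In MC38 libraries the pigment cell genes stood at a small share of their B16F10 mean, 0.0872% for Tyrp1, 0.0751% for Pmel, 0.074% for Dct, 0.091% for Mlana and 0.26% for Car14. The Y-linked gene Eif2s3y was at 10.7 to 13.6 FPKM in the 4 B16F10 libraries numbered 12 and 3, at 39.8 and 40.5 FPKM in the MC38 libraries numbered 3, and at 0.114 FPKM or less in all others. It went with the title number in both gates, so each group held libraries from animals of both sexes. Number 11 was the B16F10 pair without it, so leaving out a library of number 11 also changes the balance of sexes.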
